A study of Homo sapiens with 18 samples.

How the data were processed

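RNA levels were measured on 18 Illumina bead arrays of 1 colour. Per the labels, each array held RNA of a stable line derived from HepG2, a human liver tumour line, that carries a Flag-tagged thyroid hormone receptor beta (TRβ). The cells received a scramble control siRNA or an siRNA against KLF9 for 3 days and then triiodothyronine (T3, the active thyroid hormone) at 100 nM for 0, 8 or 24 h. The 6 groups of siRNA and time held 3 arrays each, and every array was placed in its group by its own title. Nothing in the labels states that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

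Per the labels' protocols, total RNA was extracted with a kit, checked on a Bioanalyser and amplified into biotin-labelled cRNA. The deposited intensity signals, 1 per probe and array, were not normalized, and bead counts per probe lay beside them. Per the file headers, the deposited p-values are detection p-values, which are made by setting each probe's signal against background. The submitters' processing notes name GenomeStudio and lumi, and their versions are not given in the sources used here. The authors' processed matrix holds values on a log2 scale, judged from the values themselves. The median of each of its columns was 7.04, each column ranked the probes as that array's own signals did (rank correlation 1), and the values correlated at 0.999 with quantile normalized log2 signals, with a slope of 1.07. The exact transformation behind it stays unknown. All columns of values were mapped to a sample, and 0 were left over.

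The number of arrays limits the precision of every value. Between 39.4% and 45.3% of probes were detected on an array, and the median bead number behind a probe was 20 to 22. Correlations of normalized values lay between 0.985 and 0.997 for arrays of a group and between 0.958 and 0.993 for arrays of different groups, with 0 identical pairs.

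The signals were background-corrected and normalized with neqc of limma 3.58.1 in R 4.3.3, which uses the detection p-values to estimate the background, with an offset of 16 and quantile normalization. Of 47220 probes, 22772 were kept because their detection p was under 0.05 on at least 3 of the 18 arrays. Probes were named through the platform annotation. It pairs 30107 probes with 1 symbol and 8 with several, and it does not list 17105, which stay unnamed here. The Entrez numbers of 30068 probes were found in a table of human genes (assembly GRCh38.p14, used for names only), and 0 symbols needed an update. Of the kept probes 16733 had 1 symbol. A gene was represented by its kept probe with the highest mean, so that 12451 genes were tested, of which 3339 had more than 1 kept probe. On the normalized scale the median of all probes was 6.75, the 90th percentile 12.12, and the lowest detected signal 7.11 (median over arrays).

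A model with 1 mean per group was fitted over all 18 arrays (lmFit, then eBayes with an intensity trend), and Benjamini-Hochberg adjusted p under 0.05 is called past the threshold. Adjusted p-values of genes are from this limma test throughout, and the error beside a log2 change is its SE with n = 3 arrays per group. The contrasts were T3 at 8 or 24 h against 0 h in each siRNA arm, 24 h against 8 h in the scramble arm, the KLF9 siRNA against scramble at each time, and the difference between the arms' T3 responses (an interaction). For a gene whose probe was detected on no array of one group, the fold is printed as "at least". This bound sets the bright group's mean against the dim group's mean of, per array, the higher of the lowest detected signal and the probe's own value. No fold is printed where it lies under 1 or both groups are dim.

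The 22 gene lists were tested with camera at a preset correlation between genes of 0.01, which compares a list with all other genes, and again with an estimated correlation. The test fry asked whether a list's members move, on balance, one way, without comparing them with other genes. A list needed 5 measured members. Counts over a list are given over all genes tested and adjusted over the list alone. The lists were thyroid hormone response genes, thyroid hormone receptor machinery, KLF and SP factors, hepatocyte identity, coagulation, bile acids with transport and detoxification, cholesterol synthesis, fatty acid synthesis, fatty acid oxidation, glucose metabolism, the mitochondrial chain, cell cycle, p53 targets with cell cycle inhibitors, acute phase and inflammation, interferon response, unfolded protein and amino acid stress, hypoxia and glycolysis, the clock, cytoskeleton and matrix contact, fibroblast markers, blood and endothelial markers, and housekeeping genes. For the size of the T3 response, genes whose mean T3 change over both arms passed the threshold with an absolute log2 value of at least 0.5 were used.

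Groups, comparisons, lists, tests, most alternatives and the rule for naming genes were set before the data were examined. In the T3 comparisons of the scramble arm, the siRNA comparison at 0 h and both interactions, the rule names the 10 largest rises and the 10 largest falls past the threshold, and 5 and 5 elsewhere. Except for the interactions, all 3 arrays of one group had to lie above all 3 of the other, so each such gene shows its direction on every array. KLF9, THRB and THRA are always named, with up to 4 members of a described list. Symbols of uncharacterised loci and sex-linked control genes were left out.

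The procedure was tested on simulated data with 200 of the 12451 genes changed. For T3 at 8 h in the scramble arm it recovered 52% of changes of 0.5 log2 and 91% of changes of 1 log2, with 7 false calls. For the KLF9 siRNA at 0 h it recovered 55% and 88%, with 3 false calls. For the interaction at 24 h it recovered 24% and 82%, with 11 false calls. In these simulations 0 recovered genes had the wrong direction. The simulated noise was independent between genes and held no shift with array brightness, so these rates do not cover errors from brightness.

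Alternatives were quantile normalization without background correction, the authors' processed values, no filter, a detection p of 0.01, the mean of a gene's probes, the replicate number as a block, the compared groups alone, array weights, eBayes without trend, the list tests above, and leaving out each array in turn. After the data were seen, arrays with a median raw signal above 200 were called bright, and brightness was used as a block, with fits without the bright 24 h arrays, on bright arrays alone and on dim arrays alone. The list tests were then also run without KLF9, the target of the siRNA, in any list. No sources used here name the slides, so a slide effect was not tested.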

Results

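The series holds 18 arrays of RNA from a HepG2-derived line that stably expresses tagged TRβ. Cells were given a scramble siRNA or an siRNA against KLF9, a zinc finger transcription factor of the Krüppel-like family, and then T3 for 0, 8 or 24 h, with 3 arrays in each of the 6 groups. The labels name no group kept for 8 or 24 h without T3, so each T3 response below may include changes with time alone. TRβ is a nuclear receptor that binds T3 and regulates transcription at its target genes. The study asked how cells with the KLF9 siRNA respond to T3 compared with cells given the control siRNA, and each comparison bears on 1 part of that question.

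The arrays differed in brightness along with time. All 6 arrays at 0 h were bright, with median raw signals of 292 to 368 in the scramble arm and 320 to 437 in the KLF9 siRNA arm. All 6 arrays at 8 h were dim, at 131 to 155 and 127 to 176. At 24 h the range was 107 to 391 and 158 to 286, and replicate 3 of each arm was the only bright array of its group. Normalized values are therefore given below together with counts from a fit that holds brightness as a block. The block's effect is estimated only from the 24 h groups, each with 1 bright and 2 dim arrays, and carried over to 8 h. It cannot change the siRNA differences or the interactions, since both arms held equally many bright arrays at each time.

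**Figure D1:**
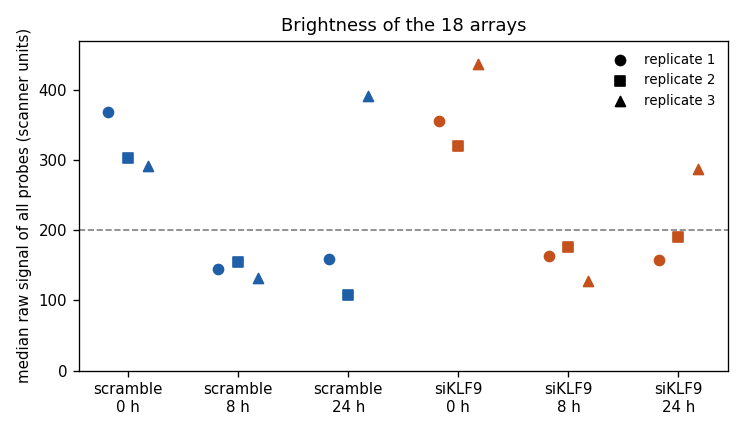
Median raw probe signal of each of the 18 arrays by group, with symbols for the replicate number and a dashed line at 200. The 8 bright arrays start at 286 and the 10 dim arrays end at 190, and every 8 h array is dim.

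Many liver transcripts lay at background in these arrays, although the labels name a HepG2 line. Of 24 hepatocyte genes on the array, 18 were detected on no array, among them the apolipoproteins APOA1 (mean normalized log2 level 6.23) and APOB (5.92), transthyretin (TTR, 6.66), alpha-fetoprotein (AFP, 6.34) and transferrin (TF, 5.83). The 3 detected on all arrays were albumin (ALB, 9.21) and the transcription factors FOXA1 (10.56) and CEBPA (9.61). Of 21 coagulation genes 13 were detected on no array, as were 16 of 25 bile acid, sterol export and drug metabolism genes. Of 13 fibroblast markers 6 were detected on all arrays, including the collagens COL1A1 (12.75), COL3A1 (13.93) and COL1A2 (12.15). All 17 housekeeping genes were detected on all arrays. Of 14 blood and endothelial markers, 3 were detected on all arrays and 9 on none.

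**Figure D2:**
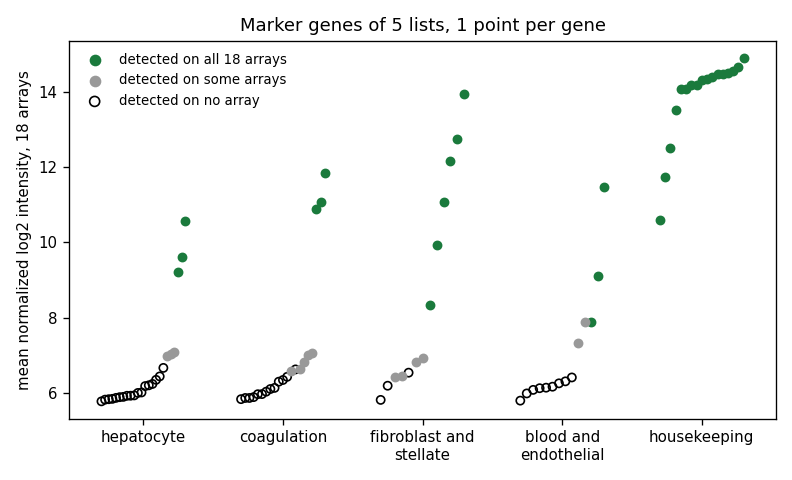
Mean normalized log2 level over the 18 arrays for the genes of 5 marker lists, with 1 point per gene and the colour showing detection on all, some or no arrays. Of the 24 hepatocyte genes 18 are detected on no array, while all 17 housekeeping genes are detected on all.

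The first question was how far the siRNA lowered its target. KLF9 stood at a mean normalized log2 level of 12.03 ± 0.09 (SD, n = 3) in scramble cells at 0 h, 13.38 ± 0.06 at 8 h and 13.30 ± 0.14 at 24 h of T3. With the KLF9 siRNA it stood at 8.41 ± 0.35, 10.64 ± 0.08 and 10.47 ± 0.06. The siRNA thus left 8.11% of the scramble level at 0 h (log2 change -3.62 ± 0.12, limma adjusted p = 4.9e-15), 15% at 8 h (-2.74 ± 0.12, adjusted p = 3.71e-13) and 14.1% at 24 h (-2.82 ± 0.12, adjusted p = 2.65e-13), and all 3 arrays lay below all 3 scramble arrays at each time. KLF9 rose with T3 in both arms, 2.53-fold at 8 h and 2.40-fold at 24 h in scramble cells and 4.69-fold and 4.18-fold in KLF9 siRNA cells. The rise was larger on the log2 scale with the siRNA, by 0.89 ± 0.17 at 8 h (adjusted p = 0.014) and by 0.80 ± 0.17 at 24 h (adjusted p = 0.0142). This difference did not pass with quantile normalization without background correction (0.50, adjusted p = 0.16, and 0.43, adjusted p = 0.173) or with the authors' processed values (0.63, adjusted p = 0.0872, and 0.55, adjusted p = 0.0878). It also missed the threshold at 8 h without KLF9 siRNA 8 h replicate 3 (0.86, adjusted p = 0.0543) and at 24 h in the compared groups alone (0.80, adjusted p = 0.0777) and on bright arrays alone (0.57, adjusted p = 0.441).

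**Figure D3:**
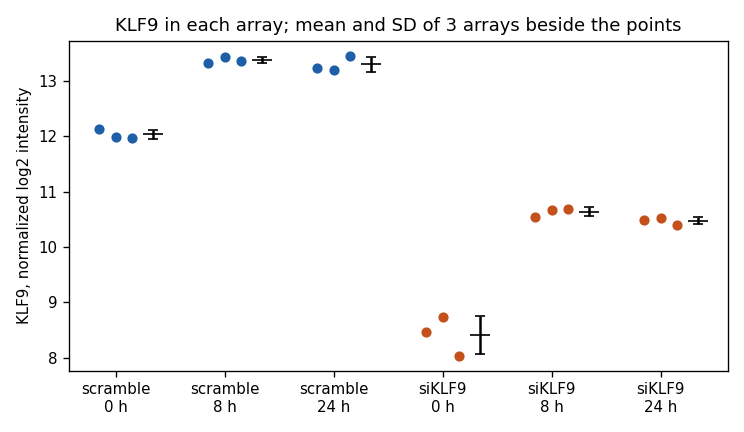
KLF9 on the normalized log2 scale by siRNA and hours of T3, with 1 point per array and the group mean and SD (n = 3) beside them. The siRNA group means stay between 8.41 and 10.64 and the scramble groups between 12.03 and 13.38, and both arms rise with T3.

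Of the receptors, THRB passed the threshold in none of the 10 comparisons by limma, and its probe lay between 7.84 and 8.23 in all 6 groups; whether it reads the tagged transgene is not known here. THRA, which encodes TRα, was lower with the KLF9 siRNA at 0 h (-1.14 ± 0.18, adjusted p = 4.78e-05), at 8 h (-1.0, adjusted p = 1.93e-04) and at 24 h (at least 1.54-fold, adjusted p = 0.00236), where its probe was detected on no KLF9 siRNA array. Its 2 further probes both gave that direction at 0 h, and 1 of them at 8 and 24 h. The 24 h call was lost with the mean of the gene's probes (-0.33, adjusted p = 0.124) and on bright arrays alone (-0.26, adjusted p = 0.686).

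T3 for 8 h in scramble cells was first set against 0 h, and T3 and elapsed time cannot be told apart in this comparison. The largest rises included MLXIPL, the glucose-responsive transcription factor ChREBP (log2 change 3.87 ± 0.24, 14.6-fold), and SMOX, a polyamine oxidase (3.11 ± 0.11, 8.66-fold). TNFRSF9, a receptor of the tumour necrosis factor family, rose 8.68-fold (3.12 ± 0.27), and the prostaglandin D2 synthase PTGDS rose 7.87-fold (2.98 ± 0.18). Genes below detection at 0 h rose at least 11-fold (the autophagy regulator TP53INP2), 9.84-fold (the epithelial sodium channel subunit SCNN1A), 8.58-fold (DNMT3L), 7.33-fold (ACSL5, which activates long-chain fatty acids), 6.54-fold (CYP24A1, which degrades vitamin D hormone) and 6.19-fold (TNFAIP2). The largest adjusted p among these 10 was 2.19e-08, for TNFRSF9.

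The largest falls at 8 h included TNFRSF11B, the decoy receptor osteoprotegerin (-2.02 ± 0.14), the chemokine CXCL1 (-1.89 ± 0.21), B4GALT6 (-1.73 ± 0.16), ANKRD1 (-1.72 ± 0.17), LHX4 (-1.71 ± 0.15), INHBE (-1.69 ± 0.12) and TRIM51 (-1.69 ± 0.16). TENT5B, CCND2 (cyclin D2) and LRRN3 fell at least 3.12-fold, 2.87-fold and 3.00-fold to below detection. The largest adjusted p among these 10 falls was 8.93e-07, for CXCL1.

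Of 12451 genes, 2585 (20.8%) passed at 8 h, 1100 higher and 1485 lower, and 196 and 95 of them changed at least 2-fold. The groups did not overlap for 5523 genes, where chance gives 10% of genes. The arrays at 8 h were all dim and those at 0 h all bright, and with brightness as a block 961 genes passed (516 higher, 445 lower), of which 835 were among the 2585. The block rests on the 24 h groups alone, so part of the drop may be lost precision. The bright scramble array there had the lowest array weight of all arrays, 0.165. Leaving out scramble 0 h replicate 1 gave 1678 genes.

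Among the gene lists, thyroid hormone response genes rose as a group at 8 h (5 of 11 measured higher, 1 lower, 5 not past, and 5 and 1 adjusted over the list alone; camera adjusted p = 1.35e-04). KLF9 is a member of this list, and without it the list passed as well (adjusted p = 9.94e-04). Of the 19 list genes on the array, 8 were detected on no array. The members that rose included the protease gene FURIN (2.52 ± 0.13), BCL3 (1.92 ± 0.14), the corepressor HR (at least 2.86-fold) and PCK1, the key enzyme of gluconeogenesis (at least 2.61-fold). Of 17 p53 targets and cell cycle inhibitors, 8 rose and 1 fell (9 and 1 adjusted over the list alone; adjusted p = 1.56e-04), with TP53I3 (2.21 ± 0.11), the inhibitor CDKN1A (2.21 ± 0.11), GADD45B (1.83 ± 0.11) and MDM2 (0.72 ± 0.15) higher. Bile acid, sterol export and drug metabolism genes had 3 of 8 higher and 1 lower (3 and 1 adjusted over the list alone; adjusted p = 0.0245, and adjusted p = 0.122 with an estimated correlation). They included the hormone FGF19 (at least 5.79-fold) and the transporter ABCC3 (2.09 ± 0.16). ABCA1, the cholesterol exporter, was lower (-0.48 ± 0.10), a call lost with brightness as a block (-0.26, adjusted p = 0.323).

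Interferon response genes had 8 of 23 higher and 3 lower (9 and 3 adjusted over the list alone; adjusted p = 0.0476, and adjusted p = 0.0877 with an estimated correlation), with IRF1 (2.03 ± 0.09), IRF9 (1.34 ± 0.14), IRF7 (1.18 ± 0.14) and IFIH1 (1.00 ± 0.13) higher. The list missed the threshold without scramble 0 h replicate 3 (adjusted p = 0.053) and with brightness as a block (0.0562). Hypoxia and glycolysis genes had 4 of 23 higher and 1 lower (4 and 1 adjusted over the list alone; adjusted p = 0.049, and adjusted p = 0.0877 with an estimated correlation), with the vasoactive peptide ADM (1.99 ± 0.07), NDRG1 (1.13 ± 0.08) and VEGFA (1.03 ± 0.13) higher. That call was lost without scramble 0 h replicate 1 (0.0579), without scramble 0 h replicate 3 (0.053), without scramble 8 h replicate 2 (0.115) and with the block (0.0678).

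Other lists did not pass at 8 h. Of 14 acute phase and inflammatory genes 3 were higher and 6 lower (3 and 7 adjusted over the list alone; adjusted p = 0.138), among them CXCL8 (-1.45 ± 0.13) and IL6 (-0.89 ± 0.13). Of 8 fibroblast markers 0 were higher and 4 lower by limma, and 1 and 5 adjusted over the list alone (adjusted p = 0.0542). PDGFRB (-0.77 ± 0.11) was among the 4. Single members of further lists that passed were the clock output factor DBP (2.36 ± 0.18), KLF10 (1.31 ± 0.13), KLF2 (-0.91 ± 0.09) and CEBPA (-0.87 ± 0.13). The endothelial marker VWF rose at least 3.51-fold.

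T3 for 24 h in scramble cells was set against 0 h next, with the same limit. The 10 largest rises included TNFRSF9 (4.56 ± 0.27, 23.5-fold), MLXIPL (3.85 ± 0.24, 14.4-fold), SMOX (3.45 ± 0.11, 11-fold) and OLR1, the receptor for oxidised low-density lipoprotein (3.42 ± 0.10, 10.7-fold). Genes below detection at 0 h rose at least 11.7-fold (SPINK4), 10.6-fold (TP53INP2, and ACSL5, with 1 of 2 further probes of ACSL5 in that direction), 10.0-fold (SCNN1A), 7.72-fold (PADI3) and 5.44-fold (CSDC2). The largest adjusted p of these 10 was 6.88e-11, for MLXIPL.

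The largest falls at 24 h were MYBPC2, a myosin binding protein (-3.65 ± 0.16, 12.5-fold), FGFBP1 (-2.83 ± 0.13, 7.09-fold) and the receptor GPR183 (-2.54 ± 0.10, 5.82-fold). TNFRSF11B (-2.36 ± 0.14), MFAP4 (-2.34 ± 0.22), the tubulin TUBB2B (-2.21 ± 0.11), the keratin KRT16 (-2.21 ± 0.19), NYNRIN (-2.18 ± 0.20) and HPD (-2.13 ± 0.23) fell as well, and CCND2 fell at least 2.82-fold. The largest adjusted p of these 10 was 4.14e-07, for HPD.

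At 24 h, 2988 genes (24.0%) passed, 1267 higher and 1721 lower, with 253 and 192 changed at least 2-fold. The groups did not overlap for 4217 genes, where chance gives 10%. With brightness as a block 2174 passed (1002 higher, 1172 lower; 1807 shared with the 2988). Leaving out the bright array, scramble 24 h replicate 3, gave 4576.

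Fibroblast markers fell as a group at 24 h (0 of 8 higher by limma, 6 lower, and the same counts adjusted over the list alone; camera adjusted p = 6.27e-04). They included the receptor PDGFRB (-1.84 ± 0.11) and COL1A1 (-0.79 ± 0.10). Decorin (DCN) was lower as well (-0.99 ± 0.16), but its other probe had the opposite direction. Thyroid hormone response genes had 5 of 11 higher and 2 lower (5 and 2 adjusted over the list alone; adjusted p = 0.0021, and 0.00863 without KLF9), with FURIN at 2.75 ± 0.13, HR at least 3.35-fold, PCK1 at least 3.31-fold and BCL3 at 1.57 ± 0.14. CPT1A, also given below with fatty acid oxidation, was among the 2 lower. The bile acid, sterol export and drug metabolism list had 4 of 8 higher and 0 lower by limma (4 and 0 adjusted over the list alone; adjusted p = 0.0021, and adjusted p = 0.0512 with an estimated correlation). ABCC3 (2.51 ± 0.16) and FGF19 (at least 3.40-fold) were among the 4. CYP1A1 was too (0.77 ± 0.20), a call lost without scramble 0 h replicate 2 (0.49, adjusted p = 0.0629) and on bright arrays alone (0.86, adjusted p = 0.128).

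Of the p53 list 6 of 17 were higher and 2 lower at 24 h (8 and 2 adjusted over the list alone; adjusted p = 0.00256), with TP53I3 at 2.60 ± 0.11 and CDKN1A at 2.12 ± 0.11. The hypoxia and glycolysis list had 7 of 23 higher and 2 lower (7 and 2 adjusted over the list alone; adjusted p = 0.00568), with ADM (2.58 ± 0.07), VEGFA (1.45 ± 0.13), NDRG1 (1.41 ± 0.08) and ANKRD37 (0.85 ± 0.11) higher. Acute phase genes (3 of 14 higher, 6 lower; 3 and 8 adjusted over the list alone; adjusted p = 0.16) and interferon genes (7 of 23 higher, 5 lower; 9 and 5 adjusted over the list alone; adjusted p = 0.269) did not pass as lists. CXCL1 (-1.64 ± 0.21), IL6 (-1.28 ± 0.13) and CXCL8 (-1.24 ± 0.13) were lower, and IRF1 (2.20 ± 0.09) and DBP (2.62 ± 0.18) higher. Of 21 fatty acid oxidation genes 0 were higher by limma and 5 lower (the same counts adjusted over the list alone; adjusted p = 0.16), among them the peroxisomal enzyme EHHADH (-0.93 ± 0.14) and CPT1A, which brings fatty acids into mitochondria (-0.69 ± 0.10). VWF rose at least 5.19-fold.

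THRA was lower at 24 h (-0.56, adjusted p = 0.0242). That call was lost without scramble 0 h replicate 1 (-0.59, adjusted p = 0.05), without scramble 0 h replicate 2 (-0.50, adjusted p = 0.0899) and without scramble 24 h replicate 3 (-0.34, adjusted p = 0.119).

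Between 8 and 24 h of T3 in scramble cells, OLR1 (2.58 ± 0.10, 5.96-fold), SPINK4 (2.43 ± 0.14), ENPP2 (2.27 ± 0.20) and SPANXD (2.09 ± 0.16, of a family of near-identical copies) rose further. TRAPPC3L rose at least 4.16-fold. MYBPC2 (-3.08 ± 0.16), the ribosomal RNA gene RNA28SN5 (-2.51 ± 0.25), HPD (-2.20 ± 0.23) and KRT16 (-1.81 ± 0.19) fell, and LEFTY1 fell at least 2.70-fold. The largest adjusted p-values were 9.87e-08 among the rises (ENPP2) and 2.05e-06 among the falls (HPD). In all, 606 genes (4.87%) passed, 293 higher and 313 lower, and the groups did not overlap for 2585, where chance gives 10%. With brightness as a block 600 passed, 505 of them shared. Without scramble 8 h replicate 2 or replicate 3 the counts were 375 and 377. Fibroblast markers were lower as a list (0 of 8 higher by limma, 2 lower; 1 and 4 adjusted over the list alone; camera adjusted p = 0.00125), with PDGFRB at -1.07 ± 0.11 and COL1A1 at -0.78 ± 0.10. KLF9 differed by -0.08 ± 0.12 (adjusted p = 0.837).

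T3 in KLF9 siRNA cells showed the response with the target lowered. At 8 h MLXIPL (3.44 ± 0.24, 10.8-fold) and TP53INP2 (3.28 ± 0.18, 9.75-fold) rose, and TNFRSF9, CYP24A1 and TNFAIP2 rose at least 13.8-fold, 7.40-fold and 6.16-fold. TNFRSF11B (-2.32 ± 0.14) and PPDPFL (-2.03 ± 0.15) fell, and CCND2 and CAVIN2 fell at least 4.13-fold and 2.68-fold. The fifth fall, PRR20D, at least 3.36-fold, was lost with brightness as a block (-0.32, adjusted p = 0.765). The largest adjusted p-values were 7.75e-10 among the rises (MLXIPL) and 0.00284 among the falls (PRR20D). In all, 3487 genes (28.0%) passed at 8 h, 1623 higher and 1864 lower, and with brightness as a block 924 passed (486 higher, 438 lower; 847 shared). The groups did not overlap for 5224 genes, where chance gives 10%.

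At 24 h in KLF9 siRNA cells TP53INP2 rose 12.7-fold (3.67 ± 0.18), and TNFRSF9, PADI3, ACSL5 and SUN3 rose at least 28.1-fold, 8.68-fold, 6.2-fold and 4.35-fold. FGFBP1 (-3.04 ± 0.13, 8.20-fold) and the protease inhibitor PI3 (-2.64 ± 0.18, 6.24-fold) fell, and MYBPC2, CCND2 and KRT16 fell at least 4.23-fold, 3.86-fold and 2.96-fold. The largest adjusted p-values were 3.93e-12 (TNFRSF9) and 1.26e-09 (KRT16). In all, 3425 genes (27.5%) passed, 1699 higher and 1726 lower, against 2061 with the block (1031 higher, 1030 lower; 1865 shared). The groups did not overlap for 5046, where chance gives 10%.

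Acute phase and inflammatory genes fell with T3 in this arm. At 8 h 1 of 14 was higher and 6 lower (1 and 8 adjusted over the list alone; camera adjusted p = 0.0337, adjusted p = 0.122 with an estimated correlation, 0.0532 with the block). The chemokines CCL2 (-2.02 ± 0.16), CXCL1 (-1.68 ± 0.21) and CXCL2 (-1.61 ± 0.17) were among the 6. At 24 h 1 was higher and 7 lower (2 and 7 adjusted over the list alone; adjusted p = 0.00451, and adjusted p = 0.0749 with an estimated correlation), with CCL2 at least 4.65-fold lower, CXCL1 at -2.29 ± 0.21 and IL6 at -1.75 ± 0.13. Fibroblast markers had 0 of 8 higher by limma and 5 lower at 8 h, the same counts adjusted over the list alone (adjusted p = 0.0337, and adjusted p = 0.122 with an estimated correlation). That call was lost without KLF9 siRNA 0 h replicate 1 (0.0617) and without KLF9 siRNA 8 h replicate 1 (0.0562). At 24 h 0 were higher by limma and 6 lower, the same counts adjusted over the list alone (adjusted p = 0.00297, and adjusted p = 0.0656 with an estimated correlation), with PDGFRB at -1.60 ± 0.11.

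Bile acid, sterol export and drug metabolism genes rose in this arm at 8 h (3 of 8 higher, 0 lower by limma, the same counts adjusted over the list alone; adjusted p = 0.0337, and adjusted p = 0.237 with an estimated correlation), a call lost without KLF9 siRNA 0 h replicate 1 (0.0713). At 24 h 5 were higher and 0 lower (the same counts adjusted over the list alone; adjusted p = 0.00297, and adjusted p = 0.0806 with an estimated correlation), with ABCC3 at 1.78 ± 0.16 at both times. Thyroid hormone response genes passed at 8 h (4 of 11 higher, 2 lower, the same counts adjusted over the list alone; adjusted p = 0.0337, and adjusted p = 0.122 with an estimated correlation), with BCL3 at 2.81 ± 0.14 and FURIN at 2.22 ± 0.13. That call rested on KLF9, and without it the list did not pass (adjusted p = 0.201). At 24 h the list did not pass (4 higher, 2 lower; 5 and 2 adjusted over the list alone; adjusted p = 0.0624, and 0.228 without KLF9).

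The T3 responses of the arms were then set against each other, which addresses the study's main question. At 8 h 1715 genes passed in both arms in the same direction (787 up, 928 down), which is 66.3% of the scramble calls, where independent lists give 143 and 222, and 4 passed in opposite directions. At 24 h 1939 did (915 up, 1024 down), or 64.9% of the scramble calls, against 173 and 239 for independent lists, and 15 went opposite ways. With brightness as a block 595 genes were shared at 8 h and 1304 at 24 h. In both arms all 0 h arrays were bright and all 8 h arrays dim, so a common shift with brightness would also give calls of the same direction. The arms share no arrays. The log2 responses of the arms correlated at 0.80 at both times across genes, which are not independent replicates.

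No difference in the size of the response was detected on balance. Over 1422 genes that responded at 8 h (764 rising, 658 falling) the median interaction, signed by the direction of the response, was 0.066, and 42.3% of genes responded less with the KLF9 siRNA. An exact permutation test of the arms gave p = 0.125 (two-sided, smallest possible 0.005), and fry gave p = 0.726 for movement one way and p = 8.39e-04 for change in either direction. Over 1542 genes at 24 h (799 rising, 743 falling) the median was 0.021, 47.5% responded less, and the exact permutation p was 0.82, with p = 0.854 and p = 5.96e-14 from fry.

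**Figure D4:**
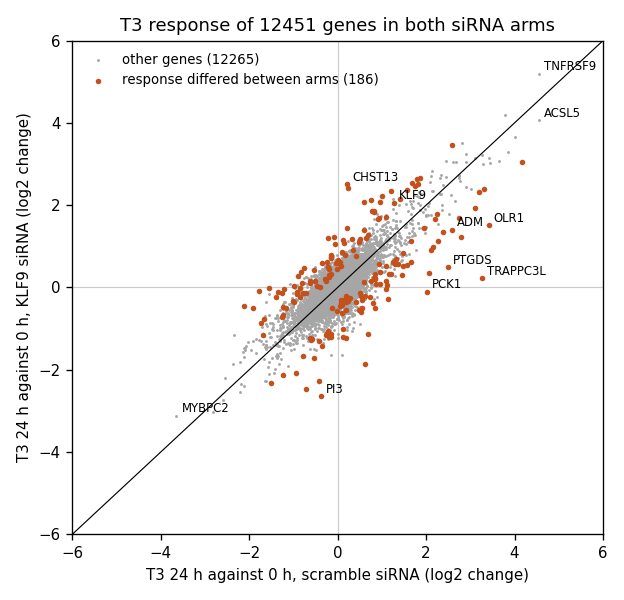
Log2 change after 24 h of T3 for 12451 genes, in scramble cells on the x axis and KLF9 siRNA cells on the y axis, with the diagonal drawn. Each point is a gene, and the 186 genes whose response differed between the arms by the interaction test are coloured.

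Single genes did respond differently. At 8 h the interaction passed for 63 genes (0.506%), with 31 above and 32 below 0, while 1139 had an unadjusted p under 0.05. Of the 63, 44 were detected on at least 1 array of each of the 4 groups. Among the 44 the response was smaller with the siRNA in size for 15, larger for 15 and opposite in sign for 14. PYGM, muscle glycogen phosphorylase (-1.49 ± 0.18; response 2.44 in scramble and 0.95 in KLF9 siRNA cells), and ADM (-0.87 ± 0.10, adjusted p = 2.49e-04; 1.99 and 1.11) rose less with the siRNA. ADM started higher with the siRNA (mean level 12.51 against 11.62 at 0 h) and stood near the scramble level at 8 h (13.62 against 13.60). PTGDS (-2.23 ± 0.26, adjusted p = 2.49e-04), TNFRSF18 (-1.78), PCK1 (-1.76 ± 0.22, adjusted p = 3.09e-04), HSD17B14 (-1.74) and LEFTY1 (-1.69) had negative interactions as well. All 5 rose in scramble cells and were detected on all 3 scramble arrays at 8 h. With the siRNA they were detected on no array at 0 h and on at most 1 at 8 h, so the size of a response could not be read in that arm. FGF19 (-1.11) was detected on no array at 0 h in either arm, so neither of its rises has a measured start. In the other direction were IL24 (1.71 ± 0.26, adjusted p = 0.0018), which was detected only with the siRNA at 8 h among these 4 groups, and CHST13 (1.26). CCL2 fell with the siRNA (-2.02), but it was detected on no scramble array at 0 or 8 h, so no fall could be read in that arm. Its interaction (-1.32) was lost with the authors' processed values (-0.86, adjusted p = 0.0677). For genes below detection in a group, values enter these differences as measured, so no fold is given.

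At 24 h the interaction passed for 186 genes (1.49%), 92 above and 94 below 0, with 1468 at an unadjusted p under 0.05. Of the 186, 148 were detected on at least 1 array of each of the 4 groups. Among the 148 the response was smaller in size for 50, larger for 49 and opposite in sign for 49. OLR1 (-1.91 ± 0.15, adjusted p = 1.48e-07; 3.42 in scramble and 1.51 in KLF9 siRNA cells) and ADM (-1.18 ± 0.10, adjusted p = 7.17e-07; 2.58 and 1.40) rose less with the siRNA. TRAPPC3L (-3.05 ± 0.22, adjusted p = 9.94e-08), PCK1 (-2.12 ± 0.22, adjusted p = 1.03e-05), PTGDS (-1.99) and TNFSF10, which encodes the death ligand TRAIL (-1.72), rose in scramble cells and were detected on no KLF9 siRNA array at 0 or 24 h, so no response could be read in that arm. OLR1 started higher with the siRNA (mean level 10.41 against 8.38 at 0 h) and ended near the scramble level at 24 h (11.92 against 11.80), and ADM ended at 13.91 against 14.20. PI3 had a more negative response (-2.26 ± 0.25; -0.38 and -2.64). CCL2 also passed (-1.77), but it was detected on no scramble array at 0 or 24 h, so its response in that arm could not be read. CHST13 (2.29 ± 0.20, adjusted p = 7.17e-07; 0.22 and 2.51), MSMB (2.19, detected only with the siRNA at 24 h among these 4 groups), carbonic anhydrase CA2 (1.5; 0.58 and 2.08) and PPL (1.43; -0.22 and 1.21) rose with the siRNA and had values near 0 or smaller without it. CHST13 was detected on only 1 of the 3 KLF9 siRNA arrays at 0 h, so its rise there starts near background. CTCFL (1.66) and DACT1 (1.54) fell in scramble cells to below detection, and CTCFL was detected on no KLF9 siRNA array at 0 or 24 h, so no fall could be read there.

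The counts of these genes rested on few arrays. At 8 h the count fell to 34 and 32 without scramble 0 h replicates 2 and 3, 39 and 35 without scramble 8 h replicates 1 and 2, and 36, 37 and 32 without KLF9 siRNA 8 h replicates 1, 2 and 3, and it was 131 without KLF9 siRNA 0 h replicate 3. At 24 h it was 121 without scramble 0 h replicate 2, and 120 and 123 without KLF9 siRNA 24 h replicates 2 and 3. With brightness as a block 110 genes passed at 8 h and 246 at 24 h, including all 63 and all 186. The arms held equally many bright arrays at each time, so the block left each difference unchanged and altered only the spread. Keeping these calls was therefore no test of brightness. On bright arrays alone, with 1 array per 24 h group, 9 passed at 24 h. The calls of PI3 (-1.92, adjusted p = 0.0686), DACT1 (1.55, 0.0686), CA2 (1.13, 0.0692), PCK1 (-1.96, 0.0769), PTGDS (-1.80, 0.0951), TNFSF10 (-1.87, 0.0951), PPL (1.63, 0.137), CCL2 (-1.75, 0.15) and CTCFL (1.61, 0.229) were lost there with their direction kept, and so were those of all interferon, acute phase and hypoxia genes named at 24 h except ADM. This fit holds fewer arrays.

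The hypoxia and glycolysis list had a more negative response to T3 with the KLF9 siRNA at both times, which share their 0 h arrays and are not independent. At 8 h 0 of its 23 genes were above 0 by limma and 1 below (0 and 5 adjusted over the list alone; camera adjusted p = 3.23e-04), and at 24 h 0 and 4 (0 and 5 adjusted over the list alone; adjusted p = 4.39e-06). The 4 were ADM, ANKRD37 (-0.65; response 0.85 in scramble and 0.20 in KLF9 siRNA cells), SLC2A3, a glucose transporter (-0.65; 0.51 and -0.14), and BNIP3 (-0.55; -0.02 and -0.57), so for BNIP3 the difference came from a fall with the siRNA. The median interaction was -0.15 at 8 h and -0.20 at 24 h. The ANKRD37 call was lost in 7 of the 12 fits that left out 1 array, with the highest adjusted p, 0.0979, without KLF9 siRNA 24 h replicate 1.

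**Figure D5:**
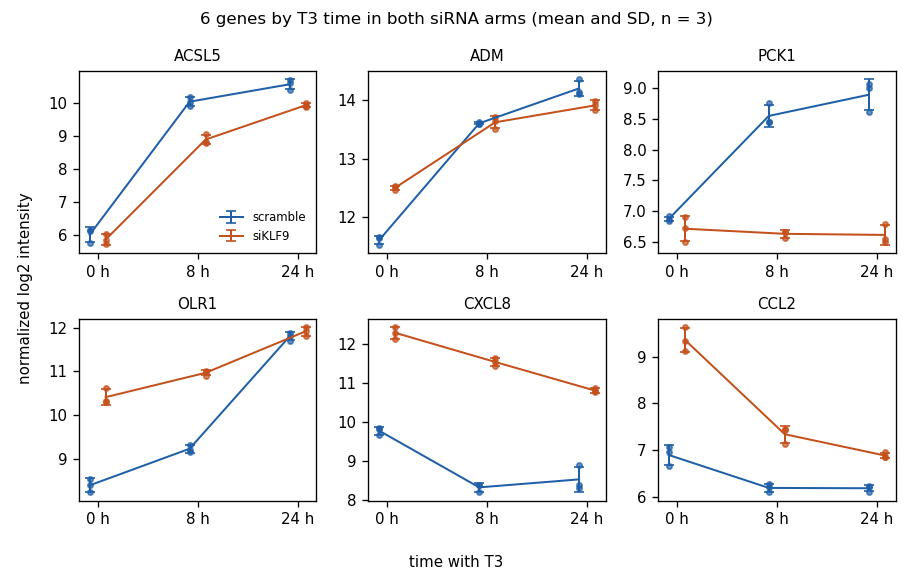
Normalized log2 level (mean and SD, n = 3) at 0, 8 and 24 h of T3, with evenly spaced times, for ACSL5, ADM, PCK1, OLR1, CXCL8 and CCL2 in both siRNA arms. ADM and OLR1 rise in both arms and less with the KLF9 siRNA, and PCK1 rises in the scramble arm and was detected on no array with the siRNA.

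At 24 h acute phase and inflammatory genes also had a more negative response with the siRNA (0 of 14 above 0 by limma, 3 below; 1 and 4 adjusted over the list alone; adjusted p = 4.7e-04). CCL2, whose scramble response could not be read, CXCL2 (-1.14) and TNFAIP3 (-0.88) were the 3. CXCL2 was detected on no scramble array at 24 h, so its fall in that arm ends at background and its difference may be overstated. The CXCL2 call was lost without scramble 0 h replicate 2 (adjusted p = 0.0523) and without KLF9 siRNA 24 h replicate 1 (adjusted p = 0.051), and that of TNFAIP3 in 4 of 12 such fits (adjusted p up to 0.0753, without scramble 0 h replicate 2). Interferon response genes had 0 of 23 above 0 by limma and 4 below (1 and 5 adjusted over the list alone; adjusted p = 0.00324), among them the RNA sensor IFIH1 (-1.02) and IFIT2 (-0.88). The list call was lost on bright arrays alone (adjusted p = 0.297). At 8 h this list had 0 above and 0 below by limma (0 and 2 adjusted over the list alone; adjusted p = 0.0293, and adjusted p = 0.0675 with an estimated correlation). It missed the threshold without scramble 8 h replicate 3 (0.0628), without KLF9 siRNA 0 h replicate 3 (0.0736) and without KLF9 siRNA 8 h replicate 1 (0.0599).

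The p53 list passed at 8 h (0 of 17 above 0 by limma, 1 below, which was CDKN1C at -0.96; 1 and 5 adjusted over the list alone; adjusted p = 0.0467, and adjusted p = 0.091 with an estimated correlation), and was lost on leaving out 9 of 12 arrays in turn, with p from 0.0616 to 0.146. The stress list passed at 24 h with 0 of 22 genes above and 0 below by limma, also adjusted over the list alone (adjusted p = 0.0111, and adjusted p = 0.155 with an estimated correlation). It was lost without scramble 0 h replicate 1 (0.0906), without scramble 24 h replicate 2 (0.0533) and on bright arrays alone (0.512).

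The siRNA comparison at 0 h asked what differed with the KLF9 siRNA before T3 was added. The series holds no further KLF9 siRNA group and no rescue group. Effects of lowering KLF9 and other effects of the siRNA therefore cannot be told apart, here or at later times. Claudin 1 (CLDN1, 3.19 ± 0.17, 9.12-fold), the Wnt inhibitor DKK1 (2.89 ± 0.14, 7.42-fold) and the interleukin 7 receptor IL7R (2.82 ± 0.14, 7.07-fold) rose. The other 7 of the 10 largest rises were ribosomal, small nuclear or small nucleolar RNAs, from RNA28SN5 (5.12 ± 0.25, 34.9-fold) through SNORD3C (3.64 ± 0.11), RNU4-1 (3.10 ± 0.13), RNA18SN5 (3.07 ± 0.26) and SNORD3D (3.07 ± 0.10) to RNU4-2 (2.79 ± 0.09), with RNU2-1 at least 6.62-fold. Of 206 small nuclear, nucleolar and ribosomal RNAs 139 were higher and 1 lower at 0 h, 141 and 1 at 8 h and 95 and 1 at 24 h. Many of these genes have near-identical copies that a probe may not separate. The largest adjusted p of these 10 was 1.26e-08, for RNA18SN5.

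After KLF9 itself, the largest falls were NFE2, a transcription factor of blood cell precursors (-3.11 ± 0.14, 8.62-fold), DDIT4L (-2.52 ± 0.15, 5.72-fold), the alanine transaminase GPT (-2.49 ± 0.20, 5.62-fold), ZNF467 (-2.40 ± 0.13), FAM83A (-2.35 ± 0.15), KCNU1 (-2.26 ± 0.14) and PLA2G3 (-2.26 ± 0.12). COXFA4L2 and CTCFL fell at least 5.96-fold and 2.91-fold. The largest adjusted p of these falls was 6.75e-09, for GPT.

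At 0 h 3769 genes (30.3%) passed, 1644 higher and 2125 lower, with 142 and 234 changed at least 2-fold. The groups did not overlap for 5189 genes, where chance gives 10%. The arrays of both groups were all bright, so brightness as a block left these differences unchanged and altered only the spread. With the block 4267 genes passed, including all 3769.

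Cholesterol synthesis genes fell (0 of 19 higher by limma, 12 lower; 0 and 13 adjusted over the list alone; camera adjusted p = 5.95e-05), with MSMO1 (-1.39 ± 0.09), lanosterol synthase LSS (-1.02 ± 0.12), mevalonate kinase MVK (-0.89 ± 0.13) and MVD (at least 1.59-fold lower) among them. Acute phase and inflammatory genes rose (8 of 14 higher, 1 lower, the same counts adjusted over the list alone; adjusted p = 5.95e-05). The chemokines CXCL8 (2.50 ± 0.13), CXCL2 (1.55 ± 0.17) and CCL2 (at least 4.59-fold) and the cytokine IL6 (1.80 ± 0.13) were higher. Fibroblast markers fell (0 of 8 higher by limma, 7 lower, the same counts adjusted over the list alone; adjusted p = 3.48e-04), with COL1A2 at -1.10 ± 0.10 and lumican (LUM) at -0.68. Hypoxia and glycolysis genes had 1 of 23 higher and 9 lower (2 and 10 adjusted over the list alone; adjusted p = 0.0123), with aldolase C (ALDOC, -2.19 ± 0.12), NDRG1 (-1.01 ± 0.08) and enolase 2 (ENO2, -0.89 ± 0.19) lower and ADM higher (0.89 ± 0.07).

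Fatty acid synthesis genes had 1 of 19 higher and 10 lower (1 and 11 adjusted over the list alone; adjusted p = 0.00215, and adjusted p = 0.131 with an estimated correlation), with ACSS2 (-1.60 ± 0.09) and the regulator SREBF1 (-1.01 ± 0.09) lower. MLXIPL of this list was lower (-0.79 ± 0.24). Its call was lost without scramble 0 h replicate 3 (-0.45, adjusted p = 0.145), KLF9 siRNA 0 h replicate 1 (-0.56, adjusted p = 0.108) or KLF9 siRNA 0 h replicate 3 (-0.70, adjusted p = 0.0607). Fatty acid oxidation genes had 0 of 21 higher by limma and 6 lower (the same counts adjusted over the list alone; adjusted p = 0.0123, and adjusted p = 0.0894 with an estimated correlation), with PDK4 at -0.89 ± 0.07. Glucose metabolism genes had 1 of 11 higher and 5 lower (2 and 5 adjusted over the list alone; adjusted p = 0.0307, and adjusted p = 0.246 with an estimated correlation), with pyruvate carboxylase (PC, -1.21 ± 0.20) and PCK2 (-1.17 ± 0.11) lower. This call was lost without KLF9 siRNA 0 h replicate 2 (0.0507).

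Cytoskeleton, adhesion and matrix genes had 10 of 21 higher and 3 lower at 0 h (10 and 4 adjusted over the list alone; adjusted p = 0.00489, and adjusted p = 0.0615 with an estimated correlation), with CCN1 (1.67 ± 0.13), ANKRD1 (1.62 ± 0.17) and thrombospondin 1 (THBS1, 1.54 ± 0.12) higher. Interferon genes went both ways, with 9 of 23 higher and 5 lower (the same counts adjusted over the list alone; adjusted p = 0.0423, and adjusted p = 0.0808 with an estimated correlation). IFIT2 (2.54 ± 0.12) and IFIT3 (1.95 ± 0.16) rose and IRF7 (-1.31 ± 0.14) fell. The list missed the threshold without KLF9 siRNA 0 h replicate 3 (0.0634), with the brightness block (0.0563) and on bright arrays alone (0.136).

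With 8 h of T3, the siRNA comparison gave RNA28SN5 (4.34 ± 0.25, 20.2-fold), SNORD3C (3.48 ± 0.11), RNU4-1 (3.29 ± 0.13) and the vasoconstrictor EDN1 (3.31 ± 0.16, 9.89-fold) higher, and SERTAD4-AS1 at least 7.16-fold higher. PTGDS (-3.35 ± 0.18, 10.2-fold), DDIT4L (-3.02 ± 0.15, 8.14-fold) and KLF9 were lower, and COXFA4L2 and NFE2 at least 10.6-fold and 7.6-fold lower. In all 3535 genes (28.4%) passed, 1637 higher and 1898 lower, and the groups did not overlap for 5814, where chance gives 10%. With 24 h of T3, RNA28SN5 (6.82 ± 0.25, 113-fold), SNORD3C (3.29 ± 0.11), SERTAD4-AS1 (3.13 ± 0.14) and RNU4-1 (3.06 ± 0.13) were higher and DACT1 at least 10.4-fold higher. PTGDS, COXFA4L2, KCNU1, NFE2 and TRAPPC3L were at least 7.14-fold, 7.07-fold, 6.68-fold, 4.82-fold and 3.87-fold lower. Here 3181 genes (25.5%) passed, 1559 higher and 1622 lower, and the groups did not overlap for 4374, where chance gives 10%. With the brightness block 3949 and 3639 genes passed, including all first calls. Both arms held equally many bright arrays at each of these times, so the block could not change these differences. Keeping the calls was therefore no test of brightness.

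Cholesterol synthesis genes were lower with the siRNA at 8 h (0 of 19 higher by limma, 13 lower; 0 and 14 adjusted over the list alone; adjusted p = 1.68e-06) and 24 h (1 and 14, the same counts adjusted over the list alone; adjusted p = 6.61e-08), with MSMO1 at -1.64 ± 0.09 and -1.81 ± 0.09 and IDI1 at -1.10 ± 0.12 and -1.23 ± 0.12. Hypoxia and glycolysis genes were lower at 8 h (0 of 23 higher by limma, 13 lower; 0 and 15 adjusted over the list alone; adjusted p = 1.68e-06) and 24 h (0 and 14; 0 and 16 adjusted over the list alone; adjusted p = 3.37e-09), with ALDOC at -2.26 ± 0.12 and -2.21 ± 0.12 and ENO2 at -1.42 ± 0.19 at 8 h. Fibroblast markers were lower at 8 h (0 of 8 higher by limma, 7 lower; 0 and 8 adjusted over the list alone; adjusted p = 3.44e-05) and 24 h (0 and 5, the same counts adjusted over the list alone; adjusted p = 5.08e-04), with COL1A2 at -1.34 and -1.20. Acute phase genes were higher at 8 h (8 of 14 higher, 0 lower by limma, the same counts adjusted over the list alone; adjusted p = 0.00122) and 24 h (5 and 0, the same counts adjusted over the list alone; adjusted p = 0.00815, and adjusted p = 0.0716 with an estimated correlation), with CXCL8 at 3.20 ± 0.13 and 2.27 ± 0.13.

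Fatty acid synthesis genes were lower at 8 h (1 of 19 higher, 11 lower; 1 and 13 adjusted over the list alone; adjusted p = 1.62e-04, and adjusted p = 0.0764 with an estimated correlation) and 24 h (1 and 8, the same counts adjusted over the list alone; adjusted p = 0.00221, and adjusted p = 0.161 with an estimated correlation). Glucose metabolism genes were lower at 8 h (1 of 11 higher, 6 lower, the same counts adjusted over the list alone; adjusted p = 0.00131, and adjusted p = 0.0764 with an estimated correlation) and 24 h (1 and 6, the same counts adjusted over the list alone; adjusted p = 0.00221, and adjusted p = 0.133 with an estimated correlation), with PCK1 at least 2.83-fold and 3.36-fold lower. Fatty acid oxidation genes were lower at 8 h (0 of 21 higher by limma, 8 lower; 1 and 9 adjusted over the list alone; adjusted p = 0.0109, and adjusted p = 0.0764 with an estimated correlation). At 24 h (1 and 4, the same counts adjusted over the list alone; adjusted p = 0.046, and adjusted p = 0.169 with an estimated correlation) the call was lost without scramble 24 h replicates 1 (0.0786) and 2 (0.0594) and without KLF9 siRNA 24 h replicates 1 (0.0819) and 3 (0.0556). On bright arrays alone it was lost too (0.281), as was the glucose metabolism call at 24 h (0.158).

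At 8 h the siRNA comparison also passed for cytoskeleton genes (7 of 21 higher, 3 lower; 8 and 3 adjusted over the list alone; adjusted p = 0.0161, and adjusted p = 0.0776 with an estimated correlation), with ANKRD1 at 2.50 ± 0.17. The thyroid hormone response list passed with KLF9, the target of the siRNA, among its lower genes (2 of 11 higher, 3 lower; 2 and 4 adjusted over the list alone; adjusted p = 0.0379, and adjusted p = 0.0764 with an estimated correlation). Without KLF9 it did not pass (2 of 10 higher, 2 lower; adjusted p = 0.239). At 24 h the unfolded protein and amino acid stress list passed (1 of 22 higher, 8 lower; 2 and 10 adjusted over the list alone; adjusted p = 0.0113, and adjusted p = 0.161 with an estimated correlation), with VLDLR at least 1.86-fold lower and asparagine synthetase (ASNS) at -0.73, and was lost on bright arrays alone (adjusted p = 0.186).

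The 9 other lists passed in no comparison. For T3 at 24 h in scramble cells they had, higher and lower, 2 and 5 of 19 receptor machinery genes (camera adjusted p = 0.702), 2 and 5 of 16 KLF and SP genes (0.593), 0 and 1 of 6 hepatocyte genes (0.925), 1 and 2 of 7 coagulation genes (0.593), 4 and 2 of 32 cell cycle genes (0.593), 3 and 3 of 15 clock genes (0.8), 3 and 1 of 34 mitochondrial chain genes (0.414), 1 and 2 of 5 blood and endothelial markers (0.902) and 1 and 0 of 17 housekeeping genes (0.702). For the KLF9 siRNA at 0 h the same lists had adjusted p-values of 0.617, 0.77, 0.842, 0.617, 0.77, 0.77, 0.934, 0.825 and 0.503. The median, mean and test differed in sign for some of these lists, such as the KLF and SP genes at 0 h (median 0.03, mean -0.14, test up).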

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

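The tests of housekeeping detection, further probes, hepatocyte transcripts and the raw signals and detected probes of the 0 h arrays, and the fits that use array brightness, were chosen only after the results they bear on were seen.

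The results given here differed between the siRNA arms by the interaction test, which compares the T3 responses directly. At 8 h 63 genes did, and of 100 splits drawn, the real one and others that mixed the arrays of the arms, only the real one reached that count (highest other 18). This share lies under the bound of 0.05 and argues against a random grouping of these arrays. It is the smallest that 100 splits can give, and the splits judge only the spread between these samples, which may be technical. At 24 h 186 genes differed between the arms, and 2 of 100 splits reached that count, the real one and 1 that gave 382. The share lies under the bound of 0.05, but another grouping of the arrays gave the larger count. Chance is therefore not clearly excluded at 24 h, and the split with 382 genes points to a structure of the samples. That split and those with 99 and 125 were among 41 other splits that placed both bright 24 h arrays in the same arm, of which 33 gave 0 genes by limma. Of the 58 other splits with these arrays in different arms, as in the real one, 56 gave 0 and the highest count was 10. With brightness as a block 246 genes passed at 24 h. This count does not bear on brightness, since both arms held equally many bright arrays and the block left each difference unchanged.

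The lists that differed at 8 h were hypoxia and glycolysis (camera adjusted p = 0.000323, median interaction -0.15), interferon response (0.0293) and p53 targets (0.0467), and the last 2 were lost with an estimated correlation (0.0675 and 0.091). At 24 h they were hypoxia and glycolysis (4.39e-06, median -0.20), acute phase genes (0.00047), interferon response (0.00324) and the unfolded protein and amino acid stress list (0.0111), which was lost with an estimated correlation (0.155). On bright arrays alone the interferon (0.297) and stress (0.512) calls were lost. For the 3 lists at 8 h, 3 of 100 splits gave as many (highest other 4). The share lies under the bound of 0.05, but another split gave more lists, so chance is not clearly excluded. For the 4 lists at 24 h, 9 of 100 did (highest other 5), so chance is not excluded for their number.

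At 8 h the response of these genes was higher with the KLF9 siRNA, by a log2 difference of 1.713 for IL24, 1.256 for CHST13, 1.112 for SERTAD4, 1.099 for TBX2, 1.072 for LINC01119, 1.063 for TRIM51, 1.06 for EDN1, 1.029 for DACT1, 1.023 for TENT5B, 1.019 for CYSRT1 and 0.887 for KLF9. It was lower by -2.225 for PTGDS, -1.78 for TNFRSF18, -1.756 for PCK1, -1.739 for HSD17B14, -1.692 for LEFTY1, -1.488 for PYGM, -1.396 for IP6K3, -1.319 for CCL2, -1.112 for FGF19, -1.095 for UNC5A, -0.959 for CDKN1C and -0.873 for ADM. PTGDS, TNFRSF18, PCK1, HSD17B14, LEFTY1, UNC5A, FGF19, LINC01119 and IL24 were detected on no KLF9 siRNA array at 0 h, EDN1 on no scramble array at 0 h, TENT5B on no array at 8 h and CCL2 on no scramble array at any time, so the sizes of these differences include values at background. Of 12 fits that left out 1 array, the call was lost in 8 for SERTAD4 (highest adjusted p 0.0852), 9 for TBX2 (0.123), TRIM51 (0.111), EDN1 (0.106), TENT5B (0.101) and UNC5A (0.143), and 11 for CYSRT1 (0.109). It was lost in 2 for LINC01119, without scramble 0 h replicate 3 (0.0619) and KLF9 siRNA 8 h replicate 3 (0.0584), and in 1 for KLF9, without KLF9 siRNA 8 h replicate 3 (0.0543).

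At 24 h the difference was 2.286 for CHST13, 2.188 for MSMB, 1.699 for RNA28SN5, 1.662 for CTCFL, 1.541 for DACT1, 1.498 for CA2, 1.432 for PPL, 1.4 for TRIM51, 1.381 for SPATA17, 1.304 for SLCO5A1 and 0.8 for KLF9. TRAPPC3L, PCK1, PTGDS, TNFSF10, CTCFL, FGF19, SPATA17 and MSMB were detected on no KLF9 siRNA array at 0 h, FGF6 on none at 24 h, FZR1 on no scramble array at 0 h, and CXCL2 and DACT1 on none at 24 h, so the same holds for them. The other probe of RNA28SN5 had the opposite direction, and the mean of its probes did not pass (0.17, adjusted p = 0.871). Lower responses were -3.046 for TRAPPC3L, -2.471 for FGF6, -2.263 for PI3, -2.118 for PCK1, -1.993 for PTGDS, -1.906 for OLR1, -1.853 for CLDN1, -1.823 for FZR1, -1.767 for CCL2, -1.723 for TNFSF10, -1.214 for FGF19, -1.179 for ADM, -1.137 for CXCL2, -1.038 for IFIT3, -1.02 for IFIH1, -1.006 for TAGLN, -0.883 for IFIT2, -0.882 for TNFAIP3, -0.857 for CDKN1C, -0.653 for ANKRD37, -0.648 for SLC2A3, -0.596 for ACTA2, -0.549 for BNIP3 and -0.536 for IRF1. Of 12 fits without 1 array, the call was lost in 8 for IRF1 (highest adjusted p 0.0912), 7 for ANKRD37 (0.0979), 6 for FZR1 (0.0938), 4 for IFIT3 (0.0628) and TNFAIP3 (0.0753) and 2 for CXCL2 (0.0523).

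Liver transcripts were at background in cells labelled as a HepG2 line, with 18 of 24 hepatocyte genes detected on no array. A loss of sensitivity or RNA large enough to hide highly expressed genes is argued against, since 100% of housekeeping genes were detected on all arrays. Their median level was 14.31, far above the lowest detected signal of 7.11, so a milder loss cannot be judged from them. A general pairing of probes with the wrong genes is argued against, since 83.6% of further probes of genes called by T3 at 24 h in scramble cells shared their gene's direction. This does not test the probes of the undetected hepatocyte genes, such as APOA1 and APOB with 1 probe each. That the arrays hold a line other than HepG2, or HepG2 cells that lost these transcripts, stays open, since both would leave the 18 genes at background. Other transcripts could bear on the identity of the line, such as CGA, INSL4 and EPCAM, described below, but were not tested for it. No biological explanation was tested.

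The T3 response at 8 h came from arrays that were all dimmer than those at 0 h, and at 24 h 1 array per arm was bright. For genes called at 8 h in the KLF9 siRNA arm with changes of at least 2-fold, the bright 24 h scramble array kept 81.4% of the change seen on the dim ones, which argues against brightness as the whole cause. For changes under 2-fold it kept 29.7%, which lies between the bounds set for a lost and a kept change and rests on 1 array, while the genes called in the scramble arm kept a ratio of 0.816 in the KLF9 siRNA arm. A part of the smaller changes may therefore come from brightness, and for them brightness and T3 cannot be told apart here.

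Small structured RNAs were higher with the KLF9 siRNA at 0 h, with 192 of 206 small nuclear, nucleolar and ribosomal RNAs above 0 (median 0.59), 139 past the threshold higher and 1 lower. Dimmer siRNA arrays are argued against, since the siRNA arrays reached 437 in median raw signal and overlapped those of the scramble arm. At 0 h 39.4% to 41.5% of probes were detected on the siRNA arrays and 41.6% to 42.8% on the scramble arrays. At 8 h, where these shares overlapped, the small RNAs were higher as well (median 0.61, 195 of 206 above 0). This argues against less sensitive siRNA arrays as the whole cause, while a part in the 0 h shift stays open. More RNA without a poly(A) tail in the labelled material would also raise replication-dependent histone mRNAs, and 78.6% of 42 such genes were above 0, while 20 (47.6%) were past the threshold higher and 2 lower. The first share meets the bound set for this explanation and the other the bound set against it. This explanation, an effect of lowering KLF9 and another effect of the siRNA on these RNAs cannot be told apart here.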

How the results depend on the processing

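The brightness fits and the lists without KLF9 were chosen after seeing the data and all other alternatives before, and the cause of each move below was not tested. Of 6866 values of named genes past the threshold over all alternatives, 6629 kept direction and call, 236 lost the call and 1 reversed; of 335 values of genes not past, 325 kept theirs, 1 passed and 9 reversed. Of 1028 list values 916 kept the call and 112 lost it, and of 535 counts and medians 445 stayed, 82 moved and 8 reversed. KLF9 stayed lower with its siRNA in all fits, with leave-one-out ranges of -3.78 to -3.44 at 0 h, -2.76 to -2.69 at 8 h and -2.87 to -2.74 at 24 h. Signal over background limits genes near detection, for which only bounds are given, and slides were not used as a block because none is named.

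Counts of genes moved as follows. With array weights they were 4224 for T3 8 h and 6105 for T3 24 h in scramble cells, 2074 for 24 h against 8 h, 5412 for the siRNA at 24 h, and 195 and 489 for the interactions at 8 and 24 h. With only the compared groups they were 1937 for T3 24 h in scramble cells, 240 for 24 h against 8 h and 94 for the 24 h interaction. With brightness as a block they were 961 and 924 for T3 8 h in scramble and KLF9 siRNA cells, 2061 for T3 24 h with the siRNA and 110 for the 8 h interaction, and 595 genes were shared between arms at 8 h. Without the bright 24 h arrays T3 24 h in scramble cells gave 4505. On bright arrays alone, with 1 array per 24 h group assumed to vary like the others, T3 24 h gave 1420 in scramble and 1200 in KLF9 siRNA cells, the siRNA at 24 h 904, the 24 h interaction 9 and the shared 24 h response 686.

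Counts of lists moved more. For 24 h against 8 h (1 list) there were 3 with quantile normalization, with the authors' values, with a detection p of 0.01, with the mean of probes, with array weights and without the bright 24 h arrays, 6 without a filter, 10 by fry, 4 with the brightness block and 2 on dim arrays. For T3 8 h in scramble cells (5) there were 3 with the mean of probes, the replicate block, the compared groups and the brightness block, 2 by camera with an estimated correlation and 14 by fry. For T3 8 h with the siRNA (4) there were 0 without a filter, with the compared groups, with array weights and with an estimated correlation, 1 with the mean of probes and 10 by fry. For T3 24 h with the siRNA (3) there were 0 without a filter and with an estimated correlation, 5 with the brightness block and 14 by fry; T3 24 h in scramble cells (5) had 17 by fry. The siRNA at 0, 8 and 24 h (9, 9 and 8) had 4, 4 and 3 with an estimated correlation and 15, 14 and 15 by fry, and 5 at 24 h on bright arrays. Without KLF9 the thyroid hormone response list lost its call for T3 8 h with the siRNA (adjusted p = 0.201) and for the siRNA at 8 h (0.239). The interactions had 1 at 8 h with an estimated correlation and 2 at 24 h on bright arrays.

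Reversed values were the median response size at 24 h with array weights (-0.047), the brightness block (-0.0053), without the bright arrays (-0.035) and on bright arrays (-0.013), and at 8 h with the block (-0.024). Also reversed were THRA for T3 8 h with the siRNA with the mean of probes (-0.0796), the block (-0.21) and without KLF9 siRNA 0 h replicate 3 (-0.0034, in a leave-one-out range up to 0.22), ANGPTL4 for the siRNA at 8 h with the mean of probes (-0.10), and THRB for the siRNA at 24 h with array weights (-0.0050), for T3 8 h in scramble cells with the block (-0.17) and for T3 24 h in scramble cells on bright arrays (-0.0280). THRA for T3 8 h in scramble cells reversed without scramble 0 h replicate 2 (0.0091) and 8 h replicate 3 (0.017), and THRB for the siRNA at 0 h without KLF9 siRNA 0 h replicate 1 (0.027, in a range from -0.19).

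Leaving out 1 array gave ranges of 1678 to 2100 (T3 8 h) and 2191 to 4576 (T3 24 h) in scramble cells, 375 to 707 (24 h against 8 h), 2424 to 3075 (T3 8 h) and 2335 to 3148 (T3 24 h) with the siRNA, and 2966 to 3513, 2795 to 3007 and 2572 to 3871 for the siRNA at 0, 8 and 24 h. Interactions ranged over 32 to 131 at 8 h and 120 to 273 at 24 h. Lists ranged over 3 to 6, 5 to 5, 1 to 3, 2 to 4, 3 to 4, 8 to 9, 9 to 9, 7 to 8, 1 to 3 and 3 to 7 in the same order, with 7 without KLF9 siRNA 0 h replicate 3. The median response size at 24 h ranged from -0.068 to 0.062. It was -0.013 without scramble 0 h replicate 3, -0.068 without scramble 24 h replicate 3 and -0.00011 without KLF9 siRNA 24 h replicate 1. The replicate numbers did not pair the arrays, since same-numbered arrays had median correlations of deviations of 0.0096, -0.0039 and 0.0031 and 4 of 18 arrays correlated best with their own number. With the replicate block the count of lists for T3 8 h in scramble cells (3) was the only count that moved over 1.5 times, and the 8 h interactions of UNC5A and CYSRT1 lost their calls (adjusted p = 0.0533 for both).

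Splits of 3 against 3 arrays make 10, too few for a share under 0.05. The real gene counts and the highest of the others were 2585 and 0, 2988 and 8, 606 and 1, 3487 and 0, 3425 and 0, 3769 and 10, 3535 and 0, and 3181 and 335, in the order above, and for lists 5 and 1, 5 and 1, 1 and 0, 4 and 0, 3 and 3, 9 and 3, 9 and 5, and 8 and 4. In the last gene comparison the split with 335 placed both bright 24 h arrays together. The blocked count was 3639, but the block leaves the differences of that comparison unchanged. For genes shared between arms 1 of 100 splits reached 1715 at 8 h (highest other 4) and 1 of 100 reached 1939 at 24 h (highest other 0). Most other splits mix 0 h and treated arrays within an arm, so the difference between times enters their spread and lowers their counts. These low counts therefore do not decide on chance, and they cannot tell T3 from brightness. For the response size 25 of 200 splits reached 0.066 at 8 h (highest other 0.106) and 164 of 200 reached 0.021 at 24 h (highest other 0.163), so chance is not excluded.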

Other observations

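JUN, CGA, INSL4, EPCAM, TAGLN, ACTA2 and CDKN1C were chosen as genes to describe only after their values were seen.

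The transcription factor JUN was higher with the KLF9 siRNA at every time, by a log2 change of 2.46 ± 0.11 at 0 h (limma adjusted p = 1.06e-12), 2.56 ± 0.11 at 8 h and 2.57 ± 0.11 at 24 h, with all 3 arrays above all 3 scramble arrays at 0 h, where its mean level rose from 8.67 to 11.13. CDKN1C, which encodes the cell cycle inhibitor p57, was lower by -1.32 ± 0.10 at 0 h (adjusted p = 4.67e-09), -2.28 ± 0.10 at 8 h and -2.18 ± 0.10 at 24 h. With T3 for 24 h it fell in KLF9 siRNA cells (-1.07 ± 0.10) and measured -0.21 ± 0.10 in scramble cells (adjusted p = 0.147), and the difference passed (-0.86, adjusted p = 0.00265). The contractile genes TAGLN and ACTA2 fell with T3 at 24 h in KLF9 siRNA cells, by -1.21 ± 0.09 and -1.23 ± 0.08. In scramble cells ACTA2 fell by -0.64 ± 0.08 and TAGLN measured -0.20 ± 0.09 (adjusted p = 0.129), and the differences passed (-1.01, adjusted p = 1.53e-04, for TAGLN and -0.60, adjusted p = 0.00955, for ACTA2). The ACTA2 difference missed the threshold with only the compared groups in the fit (adjusted p = 0.0607).

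Some transcripts outside the fixed lists stood far above background. In scramble cells at 0 h the glycoprotein hormone alpha subunit CGA had a mean normalized log2 level of 12.8 ± 0.07 (SD, n = 3), the insulin-like peptide INSL4 12.86 ± 0.16 and the epithelial adhesion molecule EPCAM 13.14 ± 0.05. All 3 were detected on all 3 arrays of every group.

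One hypothesis was that KLF9, itself raised by T3, carries much of the T3 response. It would then be likely that genes changed with the siRNA at 8 h opposite to their T3 change at 24 h. Across genes, which are not independent replicates, the siRNA effect at 8 h and the T3 change at 24 h in scramble cells, which share no arrays, had a Pearson correlation of 0.0485 and a Spearman correlation of 0.0875. Of 1345 genes called in both, 597 (44.4%) went opposite ways and 748 the same way. The correlation lies above the bound set before for this hypothesis. However, the siRNA effect at 8 h may hold changes already present at 0 h, where 3769 genes passed, and changes not due to KLF9. Such changes could hide an opposite shift. KLF9 itself still rose with T3 in KLF9 siRNA cells (4.69-fold at 8 h). The correlation therefore does not decide on the hypothesis, for the response as a whole or for single genes such as PCK1 and PTGDS. The response sizes bear on it more directly. With the siRNA, KLF9 stood at 10.64 at 8 h and 10.47 at 24 h of T3, below 12.03 in scramble cells at 0 h. Over the 1422 and 1542 responding genes the median signed interaction was still 0.066 and 0.021. These values argue against a response that, on balance, needs KLF9 above its scramble level at 0 h. Whether its relative rise matters stays open, and the responses may include changes with time or brightness.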
